A study of Rattus norvegicus with 6 samples.

How the data were processed

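Poly(A) selection or ribosomal depletion is not given in the sources used here; per the labels' protocols, total RNA of renal tissue was extracted with TRIzol and libraries were made with the VAHTS Universal V5 kit. Sequencing was on an Illumina NovaSeq, and RNA integrity was assessed on a Bioanalyzer, per the series' design text, but no integrity values were used here. The authors deposited raw counts per gene, whole numbers with no normalization, in a table with 1 column per library. Per the submitters' processing notes the tools were fastp 0.20.1, HISAT2 2.1.0 and HTSeq 0.11.2 and the genome build was Rnor_6.0; these notes give no order or role. The table also holds the authors' gene lengths, coordinates and other annotation columns. The highest gene end on chromosome 1 in the deposited table is 260398790 and the build of its coordinates is uncertain. The strand setting of the counting is not given in the sources used here, so reads of overlapping or antisense genes cannot be told apart, and counts of near-identical gene copies are uncertain. The table held 31368 genes, 20253 of them with a symbol. A further 806 of the 31368 were named as additions to the annotation and took 0.457% to 0.607% of each library's counts; they were kept.

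All columns of the table were matched to libraries by the sample titles, and 0 columns belonged to other series. The groups were Sham and CKD with 3 libraries each, and totals ran from 15918035 to 17503644 counts. Replicate libraries differed far beyond sampling noise (chi-square per degree of freedom 33.2 to 354 within groups), so none was a copy of another. Because reads carry no molecular identifiers, intervals for shares (exact binomial, 95%) cover counting error only.

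Genes were kept by edgeR's filterByExpr (minimum count 10, minimum total 15), which left 15371. TMM factors were 0.862, 0.837 and 0.893 for Sham 1, 2 and 3 and 1.19, 1.15 and 1.13 for CKD 1, 2 and 3. A quasi-likelihood model with the group as its only term was fitted with robust empirical Bayes (edgeR 4.0.16, limma 3.58.1, R 4.3.3), and p-values were adjusted by Benjamini-Hochberg over the genes tested, with a threshold of 0.05. The biological coefficient of variation was 37.5%. CPM are counts divided by the TMM-scaled library size, computed here from the deposited counts, and log2 CPM used a prior count of 2. Fold changes are CKD minus Sham on the log2 scale with their standard errors. Replicate numbers were not used as pairs.

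The 37 gene lists, the tests, the alternatives and the rule for naming genes were fixed before the data were examined. Lists with at least 3 tested members, 34 in number, were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists; 13 were called higher and 7 lower. With a correlation estimated per list camera called 0 lists (adjusted p from 0.371 to 0.94), where 0 is also a count of a harsher test on the same data and the rotation test fry called 7, or 20 for change in either direction. Some genes stand in more than 1 list (C1qa, Tgfb1 and Tgfb2, for example).

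Genes were named by this rule: the 4 higher and 4 lower genes with a symbol and the largest log2 fold change among those past the threshold, with an average log2 CPM of at least 3 and no overlap between groups; the 2 members with the smallest p of each list marked as a main list, and 1 member of each other list that was called; and Havcr1, Lcn2, Col1a1, Fn1, Acta2, Spp1, Kl, Egf and Umod whatever their values. Some genes that the rule picks are not reported here. Other genes named as the members of a list that passed, and Ccn2, were chosen after their values were seen.

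The same model was tested on simulated data made from the means, library sizes and dispersions of the CKD and Sham libraries, with 200 of 15371 genes changed. It recovered 6% of 100 genes changed 2-fold and 63% of 100 changed 4-fold, called 4 unchanged genes, and called 0 genes when nothing had been changed. In this simulation changes of 2-fold in single genes were thus mostly missed. Few genes were changed and both groups had the same dispersions, so the shares recovered need not hold for the data. Of 3 lists shifted by 1 log2 unit 3 were called and 0 others. The simulated genes were drawn independently, so this does not test list calls where the genes of a list move together. In the data the estimated correlation within a tested list ran from -0.08 (lymphatic endothelium) to 0.90 (intercalated cell).

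Alternatives were RLE, upper-quartile or no composition factors, no filter or a filter of CPM 1 in 3 libraries, a fit without robust empirical Bayes, DESeq2 1.42.0, limma-voom, a replicate block, each library left out, counts thinned to the smallest library, the 20 most abundant genes removed, an estimated correlation or fry for the lists, a test against a fold of 1.5 and an adjusted p under 0.01. Removal of mitochondrial genes and limma-voom with library weights were added after seeing the data, as were 6 further gene lists (circadian clock, PPAR-alpha targets, glucocorticoid-induced genes, straight and convoluted proximal tubule, and mitochondrially encoded mRNA).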

Results

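RNA was sequenced from renal tissue of male Sprague-Dawley rats of wild-type genotype. The design text places a model of chronic kidney disease (CKD) in rats 8 weeks old. The procedure that caused the disease is not given in the sources used here. There were 6 libraries, 3 labelled Sham (the controls) and 3 labelled CKD. Assigned counts came to 17409090, 17115199 and 15918035 in Sham 1, 2 and 3, and to 17467038, 17503644 and 17240755 in CKD 1, 2 and 3. The labels do not say that the libraries came from separate animals, so the p-values measure the spread between these samples, which may be technical.

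The single comparison of the design asks which genes differ in renal tissue between CKD and Sham. Havcr1, which encodes the tubular injury marker KIM-1, rose from 3.18 ± 0.71 to 150 ± 108 CPM (counts scaled to library size; mean ± SD, n = 3 per group). Spp1, which encodes the secreted phosphoprotein osteopontin, rose from 283 ± 295 to 6219 ± 3222 CPM. Tgfb2, a profibrotic growth factor, rose from 5.27 ± 2.51 to 53.9 ± 7.78 CPM. Pdk4, the kinase that turns off pyruvate dehydrogenase when fatty acids are burned, fell from 356 ± 93.4 to 16.5 ± 2.68 CPM. Gene lists of extracellular matrix, macrophages, lymphocytes, complement and interferon response were higher in CKD, and those of fatty acid oxidation and oxidative phosphorylation were lower, by a test with a preset correlation between genes. With a correlation estimated for each list, camera called 0 of the 34 lists; of the lists named here B and plasma cells had an adjusted p = 0.37 and each other list an adjusted p = 0.51.

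By edgeR's quasi-likelihood test, 587 of 15371 genes passed an adjusted p of 0.05, 411 higher and 176 lower in CKD. Of these, 403 higher and 171 lower genes had a log2 fold change of at least 1 in size. Pdk4 had the smallest adjusted p (0.0109). The 3 CKD libraries did not overlap the 3 Sham libraries in 4800 genes, or 31.2% of those tested, where chance gives 10%. Leaving out CKD 1 or CKD 2 left 0 genes past the threshold in edgeR (2330 and 2312 at an unadjusted p under 0.05), leaving out Sham 2 or Sham 3 left 2 (0 higher, 2 lower) and 7 (1 higher, 6 lower), and leaving out Sham 1 gave 1711, of which 789 were higher and 922 lower. Every gene called here thus lost its call without CKD 1 and without CKD 2, while all 587 kept their direction. With scaling by library totals alone, which moved the median fold change of all genes by 0.42 on the log2 scale, 2047 genes were higher and 181 lower, so that 91.9% of the calls were higher in place of 70.0%. The balance turned the other way without Sham 1, Sham 2 or Sham 3 and in limma-voom with library weights, chosen after the data were seen (186 higher, 301 lower).

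The largest rises among abundant, non-overlapping genes were those of A2m, C4b, Car3 and Havcr1. A2m, an acute-phase protease inhibitor of the rat, had 3, 2 and 1 counts in the Sham libraries against 368, 1057 and 93 in CKD. C4b, a complement component, had a log2 fold change of 6.75 ± 1.09 (SE; edgeR adjusted p = 0.0335), and Car3, a carbonic anhydrase, one of 6.25 ± 0.99 (edgeR adjusted p = 0.0323). For Havcr1 it was 5.56 ± 0.67 (edgeR adjusted p = 0.0278). The largest falls were those of Cyp2c11, Anxa13, Hmox1 and Slco1a1. Cyp2c11, a cytochrome P450 of male rats, had 1622, 377 and 225 counts in Sham and 0, 0 and 13 in CKD, and its log2 fold change moved from -7.80 to -12.72 without CKD 3. Anxa13, an annexin, fell by 5.80 ± 1.01 on the log2 scale, and the organic anion transporter Slco1a1 fell by 5.70 ± 1.18 (edgeR adjusted p = 0.0386 and 0.047). Hmox1, which encodes the heme-degrading enzyme heme oxygenase, fell by 5.71 ± 0.88 (edgeR adjusted p = 0.0316), with 3626, 3157 and 21116 counts in Sham 1, 2 and 3 against 221 to 264 in CKD. Reads of C4b and of Cyp2c11 can be shared with close relatives (C4a and other members of the Cyp2c family), so their counts are uncertain. In the coordinates of the deposited table, Havcr1 lies on chromosome 10 from 31119088 to 31151698 and Pdk4 on chromosome 4 from 33589799 to 33601850. The processing notes name the build Rnor_6.0, but the build of these coordinates is uncertain.

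**Figure D1:**
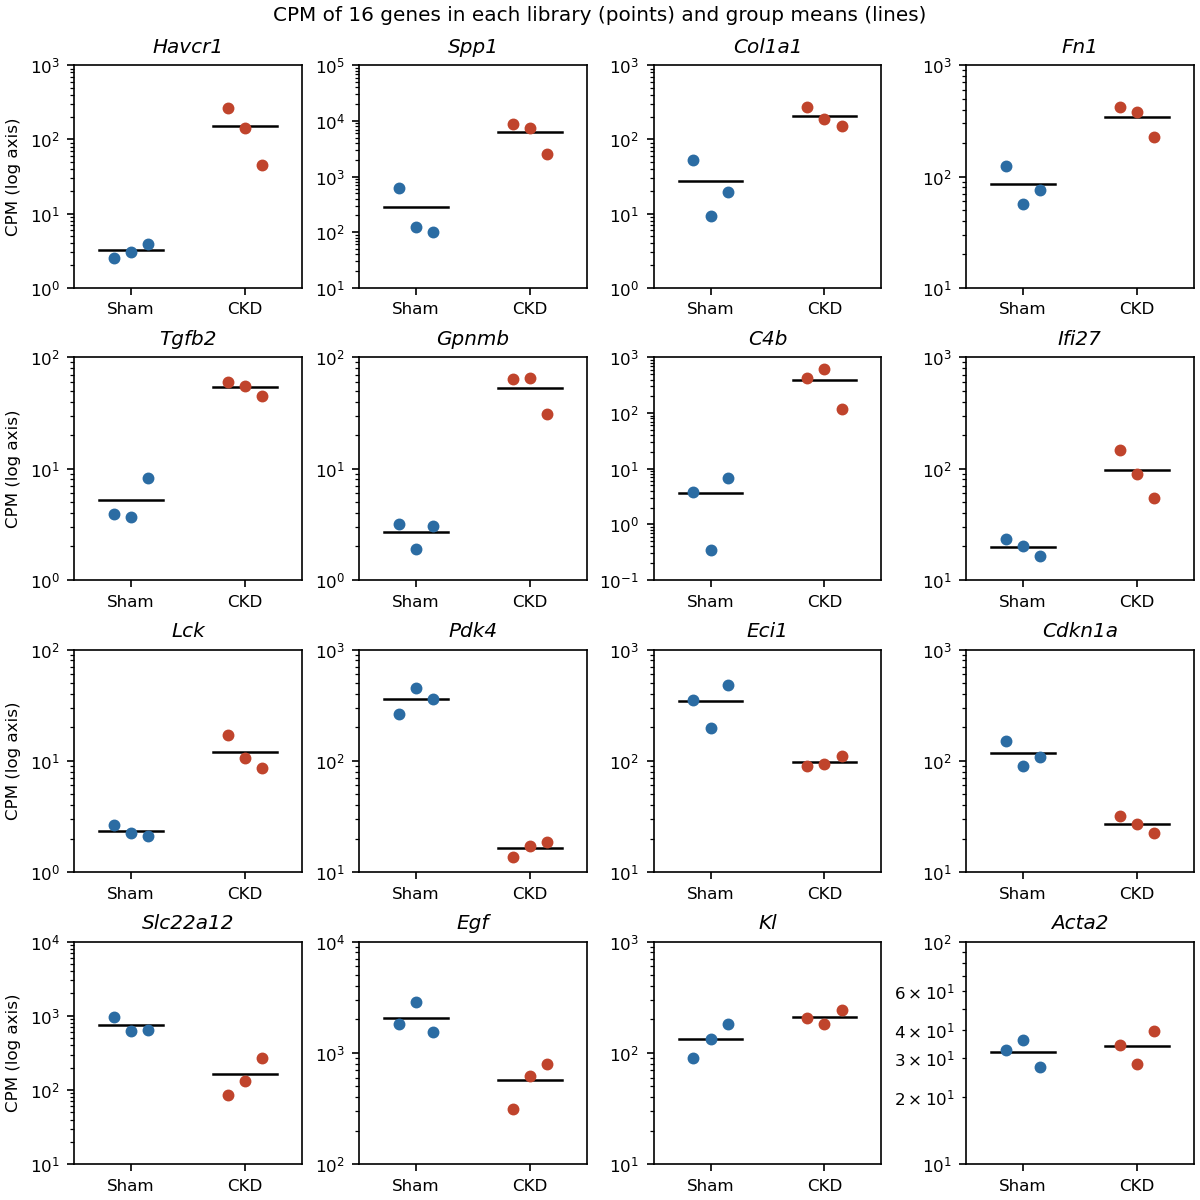
CPM of 16 named genes in each library, on log axes. Points are the 3 Sham (blue) and 3 CKD (red) libraries and lines are group means; Havcr1 runs from a Sham mean of 3.18 to a CKD mean of 150, whereas Acta2 has a Sham mean of 32.0 and a CKD mean of 33.97.

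Tubular injury and the nephron segments. Of 26 tested genes of the tubular injury list, 6 rose and 1 fell over all genes tested, and 14 were higher and 3 lower when adjusted over the list alone. The 14 became 6 without Sham 3, 8 without CKD 2 and 9 without Sham 1 or CKD 1. Havcr1, Spp1, Vim (the filament protein vimentin), Tmsb10, Cd44 (a hyaluronan receptor) and Sox4 rose. Cdkn1a, which encodes the cell cycle inhibitor p21, fell by 2.11 ± 0.26 on the log2 scale (edgeR adjusted p = 0.0278), against the direction of its list. Lcn2, the urinary injury marker NGAL, stood at 10.4 ± 1.31 CPM in Sham and 45.6 ± 36.2 in CKD, without passing (edgeR adjusted p = 0.0656), and its log2 fold change of 2.13 was 1.25 without CKD 1. The list was called higher (median log2 fold change 1.01, camera adjusted p = 0.00273), with an adjusted p = 0.51 with an estimated correlation.

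Of 30 proximal tubule genes, 0 passed the threshold in edgeR over all genes tested or adjusted over the list alone. Their median log2 fold change was -0.11 (0.30 with library totals alone; camera adjusted p = 0.767), and its sign turned with the library left out. It was -0.53 without Sham 2, when the list was called lower (camera adjusted p = 0.0167), but 0.11 without Sham 1 and 0.22 without Sham 3 (camera adjusted p = 0.60 and 0.0589), and without Sham 3 there were 5 higher and 1 lower when adjusted over the list alone. The urate transporter Slc22a12 had a log2 fold change of -2.20 ± 0.48 and the carnitine transporter Slc16a9 one of 1.10 ± 0.46, which was 0.70 without Sham 2 (edgeR adjusted p = 0.0514 and 0.197). The thick ascending limb list was called lower (median -0.81 over 14 genes, camera adjusted p = 0.00738; adjusted p = 0.51 with an estimated correlation), although 0 members passed over all genes and 2 were lower when adjusted over the list alone (0 without Sham 2, CKD 1, CKD 2 or CKD 3). That call was lost without Sham 1 (median -0.31, camera adjusted p = 0.192). Egf, the epidermal growth factor made in the distal nephron, had means of 2070 ± 703 CPM in Sham and 575 ± 245 in CKD, and Cldn16, a tight junction protein of magnesium reabsorption, of 33.7 ± 7.93 and 17.8 ± 2.50 (edgeR adjusted p = 0.0704 and 0.0785). Umod, the urinary protein uromodulin, had a log2 fold change of -1.02 ± 0.66, which was -0.23 without Sham 1 (edgeR adjusted p = 0.385).

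The collecting duct principal cell list (median -1.10 over 11 genes) and the intercalated cell list (median -1.29 over 12) were called lower, each with a camera adjusted p of 0.0178. With an estimated correlation the adjusted p = 0.51 and the adjusted p = 0.57. In both lists 0 members passed in edgeR, over all genes or adjusted over the list alone. Without Sham 1, 3 intercalated cell genes fell over all genes, and 9 intercalated and 7 principal cell genes were lower when adjusted over the list alone (medians -1.77 and -1.50). Both calls were lost without Sham 2, where the medians were -0.20 and -0.39 (camera adjusted p = 0.281 and 0.408), and the intercalated call also without CKD 1 (-1.15, camera adjusted p = 0.0531). The water channel Aqp3 had a log2 fold change of -1.10 and the sodium pump regulator Fxyd4 of -1.83, or -0.70 and -1.21 without Sham 2, and the anion exchanger Slc4a1 one of -2.08, or -1.22 without Sham 2 (edgeR adjusted p = 0.121, 0.0871 and 0.102). Sham 2 also had the highest share of mitochondrial counts, 37.9% against 14.4% and 15.3% in Sham 1 and Sham 3. The distal convoluted and connecting tubule list was not called (median -0.28 over 10 genes, camera adjusted p = 0.644), and its median was 0.14 with library totals alone and 0.21 without Sham 2. Without Sham 1 this list had a median of -0.60 (camera adjusted p = 0.0665), with 1 member lower over all genes and 2 lower when adjusted over the list alone. Its members with the smallest p, the kallikrein Klk1 and the kinase Stk39, had log2 fold changes of -1.94 and -0.94, or -0.71 and -0.49 without Sham 2. For podocytes (14 genes, camera adjusted p = 0.534) the median was 0.13, but -0.25 without Sham 1 and -0.05 without CKD 3. Of these genes 0 passed over all genes and 2 were higher when adjusted over the list alone (0 without Sham 2, CKD 1, CKD 2 or CKD 3). Without Sham 1, 1 podocyte gene was lower over all genes, and 2 were higher and 3 lower when adjusted over the list alone. Kirrel1, of the slit diaphragm, had a log2 fold change of 1.41 ± 0.34 (edgeR adjusted p = 0.0637).

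**Figure D2:**
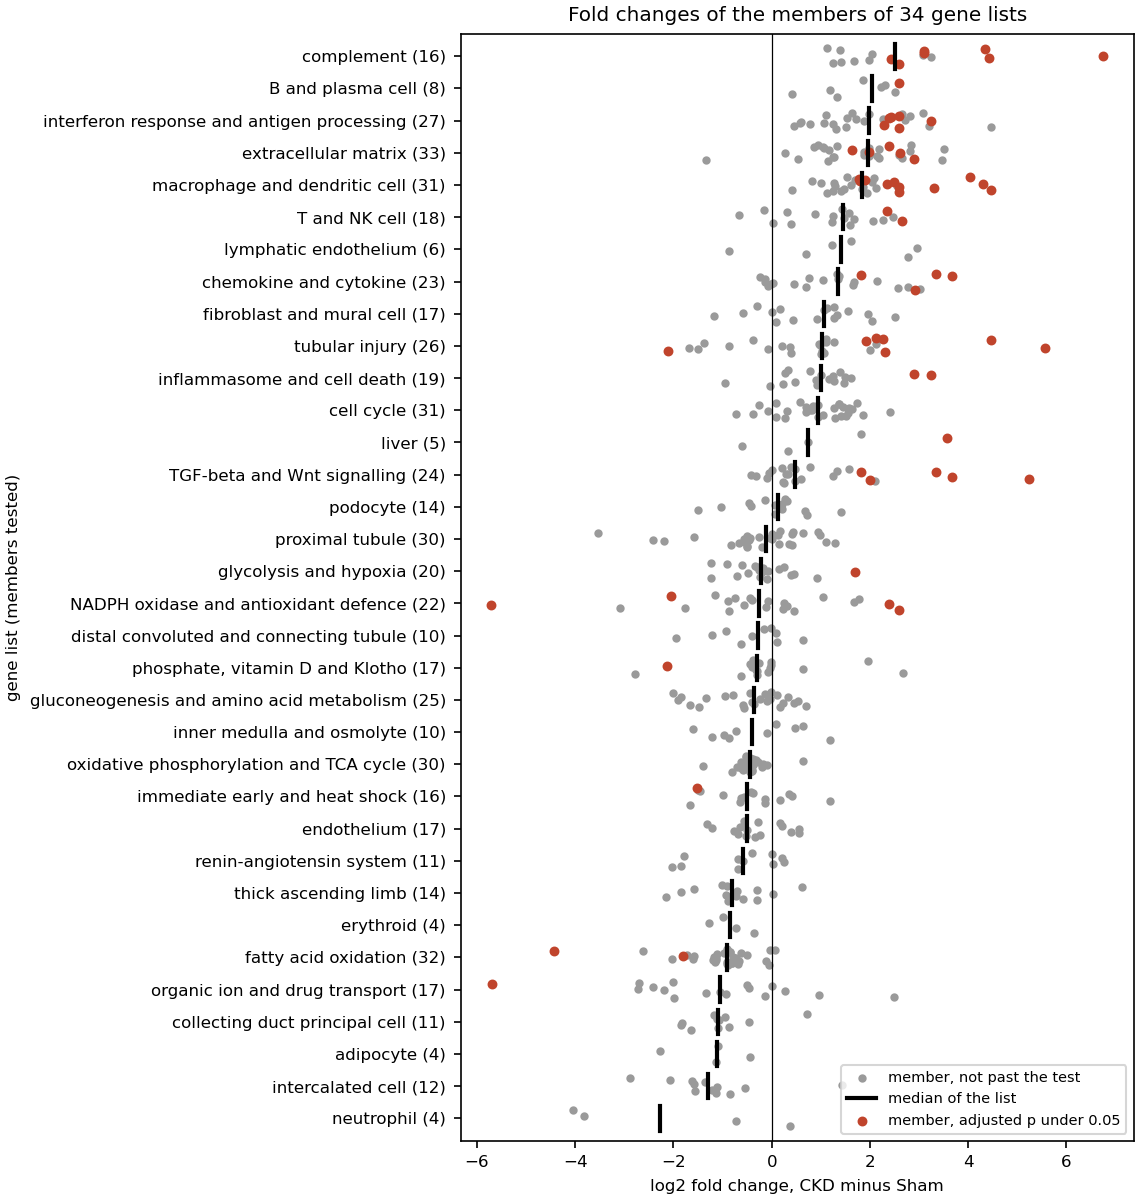
Log2 fold change, CKD minus Sham, of each member (points) of the 34 gene lists tested, with list medians as black bars and members at an adjusted p under 0.05 in red. Medians run from -2.27 for the 4 neutrophil genes to 2.51 for the 16 complement genes.

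Extracellular matrix and fibroblasts. Of 33 matrix genes 5 rose over all genes tested, namely Fn1, Col1a1, Fbn1, Mmp14 and Timp1, and 25 were higher (14 without CKD 1) and 1 lower when adjusted over the list alone. Col1a1, a chain of type I collagen, rose from 27.4 ± 23.1 to 205 ± 62.4 CPM and Fn1, fibronectin, from 86.0 ± 34.8 to 341 ± 103 CPM (edgeR adjusted p = 0.0493 and 0.0415). Mmp14, a membrane-bound matrix protease, rose by a log2 fold change of 1.64 ± 0.23 and Timp1, an inhibitor of matrix proteases, by 2.39 ± 0.43 (edgeR adjusted p = 0.0285 and 0.0394). The lower member was Ccn2, connective tissue growth factor, at 602 CPM in Sham and 239 in CKD. The matrix list was called higher (median 1.96, camera adjusted p = 3.6e-10; adjusted p = 0.51 with an estimated correlation).

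Of 17 fibroblast and mural cell genes 0 passed over all genes and 6 were higher when adjusted over the list alone, but 0 without Sham 3 or CKD 1 (median 1.06, camera adjusted p = 0.00738; adjusted p = 0.51 with an estimated correlation). Fbln1, a matrix glycoprotein, had a log2 fold change of 2.52 ± 0.54 and Des, the filament protein desmin, one of 1.26 ± 0.29 (edgeR adjusted p = 0.0503 and 0.0548). Acta2, smooth muscle actin and the usual marker of myofibroblasts, stood at 32.0 ± 4.46 CPM in Sham and 33.97 ± 5.64 in CKD (log2 fold change 0.09 ± 0.22, edgeR adjusted p = 0.844; 0.51 with library totals alone and -0.08 without Sham 3). Of 24 genes of TGF-beta and Wnt signalling 5 rose, namely Tgfb1, Tgfb2, Fzd1, Ltbp2 and Inhba, and 6 were higher when adjusted over the list alone (10 without Sham 1). That list was called higher (median 0.48, or 0.82 without Sham 1; camera adjusted p = 0.000112; adjusted p = 0.51 with an estimated correlation). Tgfb2 had a log2 fold change of 3.35 ± 0.36 and Tgfb1 one of 1.81 ± 0.31 (edgeR adjusted p = 0.0278 and 0.0365).

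Immune cells, complement and interferon. All 31 macrophage and dendritic cell genes had a positive fold change, 11 rose over all genes tested and 28 were higher when adjusted over the list alone. Gpnmb, a glycoprotein of lipid-laden macrophages, rose from 2.70 ± 0.71 to 53.6 ± 19.4 CPM and the mannose receptor Mrc1 rose by 2.49 ± 0.34 on the log2 scale (edgeR adjusted p = 0.0278 and 0.0285). Macrophage genes were called higher as a list (median 1.83, camera adjusted p = 7.4e-14; adjusted p = 0.51 with an estimated correlation). Of 18 T and NK cell genes 2 rose, the kinase Lck (2.35 ± 0.36 on the log2 scale) and the receptor chain Cd3g (2.64 ± 0.49), and 9 were higher when adjusted over the list alone (edgeR adjusted p = 0.0316 and 0.0399). The 9 became 2 without CKD 1, 3 without Sham 3, 5 without CKD 2 and 6 without Sham 1. Of 8 B and plasma cell genes 1 rose, the plasma cell chaperone Mzb1 (0.41 ± 0.13 to 2.52 ± 0.08 CPM, edgeR adjusted p = 0.0397), and 5 were higher when adjusted over the list alone (1 without Sham 3). These lists were called higher, with camera adjusted p = 2.5e-05 (T and NK) and 6.1e-05 (B and plasma). With an estimated correlation the adjusted p = 0.51 and the adjusted p = 0.37.

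All 16 complement genes had a positive fold change, 7 rose over all genes and 15 were higher when adjusted over the list alone (10 without CKD 1). The anaphylatoxin receptor C3ar1 rose by 4.42 ± 0.59 on the log2 scale (edgeR adjusted p = 0.0285). Of 27 genes of interferon response and antigen processing 6 rose and 21 were higher when adjusted over the list alone (10 without Sham 3), and Ifi27 rose from 19.9 ± 3.40 to 97.3 ± 46.5 CPM (edgeR adjusted p = 0.0336). Of 23 chemokine and cytokine genes 4 rose, namely Tgfb1, Tgfb2, Ccl19 and Lif, and 9 were higher when adjusted over the list alone (3 without Sham 3). Of 19 inflammasome and cell death genes 2 rose, the adaptor Pycard (2.90 ± 0.43 on the log2 scale, edgeR adjusted p = 0.0316) and the sensor Nlrp3, and 12 were higher and 1 lower when adjusted over the list alone. Those 12 became 2 without Sham 1, CKD 1 or CKD 2, 3 without Sham 3 and 8 without Sham 2. Medians were 2.51 for complement, 1.98 for interferon, 1.36 for chemokines and 0.99 for inflammasome genes. These lists were called higher, with camera adjusted p = 3.8e-09, 1.6e-08, 8.5e-05 and 0.000112, and each had an adjusted p = 0.51 with an estimated correlation. Of 6 lymphatic endothelium genes 0 passed over all genes and 3 were higher when adjusted over the list alone. This list was called higher (median 1.41, camera adjusted p = 0.0239; adjusted p = 0.51 with an estimated correlation), but not without Sham 1 (camera adjusted p = 0.0665) or with library totals alone (camera adjusted p = 0.0808). Ccl21, the chemokine of lymphatic vessels, had means of 4.98 ± 4.18 and 34.2 ± 7.80 CPM (edgeR adjusted p = 0.0543). The rotation test fry called the B and plasma cell, TGF-beta and Wnt, lymphatic, fibroblast, macrophage, T and NK cell, and complement lists, all higher in CKD.

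Metabolism. Of 32 genes of fatty acid oxidation 31 had a negative fold change, 2 fell over all genes tested and 16 were lower when adjusted over the list alone. That 16 hung on single libraries, being 26 without Sham 2, 11 without Sham 1, 2 without Sham 3 and 1 without CKD 1, CKD 2 or CKD 3, and on the scaling, being 1 with library totals alone (median -0.50). Pdk4 fell by 4.43 ± 0.31 on the log2 scale, and Eci1, a mitochondrial enzyme that handles unsaturated fatty acids, fell from 344 ± 143 to 97.9 ± 10.1 CPM (edgeR adjusted p = 0.0109 and 0.0415). Fatty acid oxidation was called lower as a list (median -0.91, camera adjusted p = 1.0e-09; adjusted p = 0.51 with an estimated correlation). Of 30 nuclear genes of oxidative phosphorylation and the TCA cycle 29 had a negative fold change, but 0 passed in edgeR over all genes or adjusted over the list alone; without Sham 2, 21 were lower when adjusted over the list alone. Cytochrome c (Cycs) stood at 127 ± 62.3 CPM in Sham and 48.3 ± 10.9 in CKD, and Cox7a2, a subunit of cytochrome c oxidase, at 141 ± 28.4 and 86.8 ± 12.5 (edgeR adjusted p = 0.0755 and 0.119). The list was called lower (median -0.45, camera adjusted p = 1.7e-05; adjusted p = 0.51 with an estimated correlation); its median was -0.04 with library totals alone, where all genes had shifted by 0.42. The share of counts on mitochondrial genes was 14.4%, 37.9% and 15.3% in Sham and 8.88%, 8.83% and 10.8% in CKD, so that all 3 CKD libraries lay under all 3 Sham libraries. For 3 against 3 an exact two-sided permutation test cannot go under p = 0.1. The 95% exact binomial intervals of these shares cover counting error only. They ran from 14.40 to 14.44%, 37.88 to 37.93% and 15.24 to 15.27% in Sham. In CKD they ran from 8.86 to 8.89%, 8.82 to 8.85% and 10.79 to 10.82%.

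Of 20 glycolysis and hypoxia genes 1 rose, the hexokinase Hk2 (3.75 to 12.2 CPM, edgeR adjusted p = 0.0438), and 1 was higher and 1 lower when adjusted over the list alone (median -0.22, or 0.20 with library totals alone; camera adjusted p = 0.236). Of 25 genes of gluconeogenesis and amino acid metabolism 0 passed in edgeR either way, and the list was not called (median -0.36, or 0.04 with library totals alone; camera adjusted p = 0.0894) except without Sham 2, without CKD 3 or with library totals alone (camera adjusted p = 0.000297, 0.0262 and 0.0108).

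Transport, hormones, proliferation and handling. Of 17 organic ion and drug transporters 1 fell, Slco1a1, and 1 was higher and 4 lower when adjusted over the list alone (7 lower without Sham 2 and 0 without CKD 2). The list was called lower (median -1.06, camera adjusted p = 0.0317; adjusted p = 0.51 with an estimated correlation). The call was lost without Sham 1 (median -0.40), Sham 3 (camera adjusted p = 0.275) or CKD 1 (median -0.97), and without Sham 2 the median was -1.61. Of 17 genes of phosphate, vitamin D and Klotho 1 fell, the phosphate transporter Slc20a1 (167 ± 67.3 to 37.9 ± 4.87 CPM, edgeR adjusted p = 0.0325), and 2 were lower when adjusted over the list alone (median -0.29, or 0.13 with library totals alone; camera adjusted p = 0.284). Cyp24a1, the enzyme that breaks down vitamin D, had a log2 fold change of -2.79 ± 0.70, or -1.56 without Sham 3 (edgeR adjusted p = 0.0689). Kl, which encodes the anti-ageing co-receptor Klotho, stood at 135 ± 45.7 CPM in Sham and 209 ± 31.2 in CKD (log2 fold change 0.64 ± 0.30, edgeR adjusted p = 0.242; 0.37 without Sham 1). Of 11 genes of the angiotensin system 0 passed in edgeR either way (median -0.59, camera adjusted p = 0.0894), and the list was called lower only without CKD 3 or with library totals alone among the settings tried (camera adjusted p = 0.0331 and 0.0344). Its member Atp6ap2, an accessory subunit of the vacuolar proton pump, had a log2 fold change of -0.59 ± 0.22 (edgeR adjusted p = 0.165).

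Of 22 genes of NADPH oxidase and antioxidant defence the oxidase subunits Cybb and Ncf1 rose and Hmox1 and the sulfiredoxin Srxn1 fell, and 3 were higher and 3 lower when adjusted over the list alone (median -0.26, or 0.15 with library totals alone and -0.63 without Sham 2, where 6 were lower in the list alone; camera adjusted p = 0.294). Of 31 cell cycle genes 27 had a positive fold change, but 0 passed in edgeR over all genes or adjusted over the list alone. The helicase subunits Mcm6 and Mcm5 had log2 fold changes of 1.26 ± 0.32 and 1.58 ± 0.42 (edgeR adjusted p = 0.0705 and 0.0755). The list was called higher (median 0.95, camera adjusted p = 0.00114; adjusted p = 0.51 with an estimated correlation), and its median was 0.45 without CKD 1. Of 16 immediate early and heat shock genes, which respond to the handling of tissue, 1 fell, the mRNA decay factor Zfp36 (296 ± 71.1 to 103 ± 27.3 CPM, edgeR adjusted p = 0.0433), and 2 were lower when adjusted over the list alone (6 without Sham 2 or CKD 2, 0 without Sham 3 or CKD 1). Immediate early genes were called lower as a list (median -0.49, camera adjusted p = 0.0113; adjusted p = 0.51 with an estimated correlation), but not without Sham 1 (camera adjusted p = 0.114) or CKD 3 (median -0.28, camera adjusted p = 0.0829).

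Markers of other cells that a piece of kidney can hold were not called. Medians were -0.50 for endothelium (17 genes, camera adjusted p = 0.102), -0.41 for inner medulla and osmolyte genes (10 genes, 0.456; 0.03 with library totals alone), -2.27 for neutrophils (4 genes, 0.134), -1.12 for adipocytes (4 genes, 0.138), -0.86 for erythroid cells (4 genes, 0.0894) and 0.74 for liver (5 genes, 0.15), in which Fgb, a fibrinogen chain, rose. With 1 library left out the liver median ran from 0.35 to 1.68, and that of endothelium was -0.27 without Sham 2. Of these the neutrophil list was called lower without Sham 1, CKD 1, CKD 2 or CKD 3 (medians -4.50, -4.03, -3.60 and -3.84), with library totals alone (-1.84) and with no filter (-3.85). More neutrophil genes were tested in some of these fits (6 without Sham 1 or CKD 1, 11 with no filter), so their medians are not of the same 4 genes. The adipocyte list was called lower without Sham 3 (-1.55) and with library totals alone (-0.69), but without Sham 1 its median was -0.38 (camera adjusted p = 0.802). The erythroid list was called lower without Sham 1 (-1.27), without CKD 2 (-1.19), with library totals alone (-0.45) and with the replicate block (-0.80). Lists of urothelium, adrenal and skeletal muscle had 1, 2 and 1 genes past the count filter and were not tested as lists. Both adrenal genes were lower when adjusted over the list alone, with no overlap between groups (median -2.57; chance gives 10% per gene). With 3 genes past the filter the adrenal list was called lower without Sham 2, Sham 3, CKD 1 or CKD 2 (camera adjusted p = 0.0263, 0.0192, 0.0244 and 0.0151).

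The libraries of the control group spread more than those of the CKD group. Spearman correlations of log2 CPM between libraries were 0.905 to 0.951 within Sham and 0.965 to 0.982 within CKD. The first principal component, with 52.3% of the variance, separated the groups, and the second, with 25.9%, set Sham 1 apart from Sham 2. Group membership accounted for 48.8% of the variance of log2 CPM, and for 62.8% without Sham 1.

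**Figure D3:**
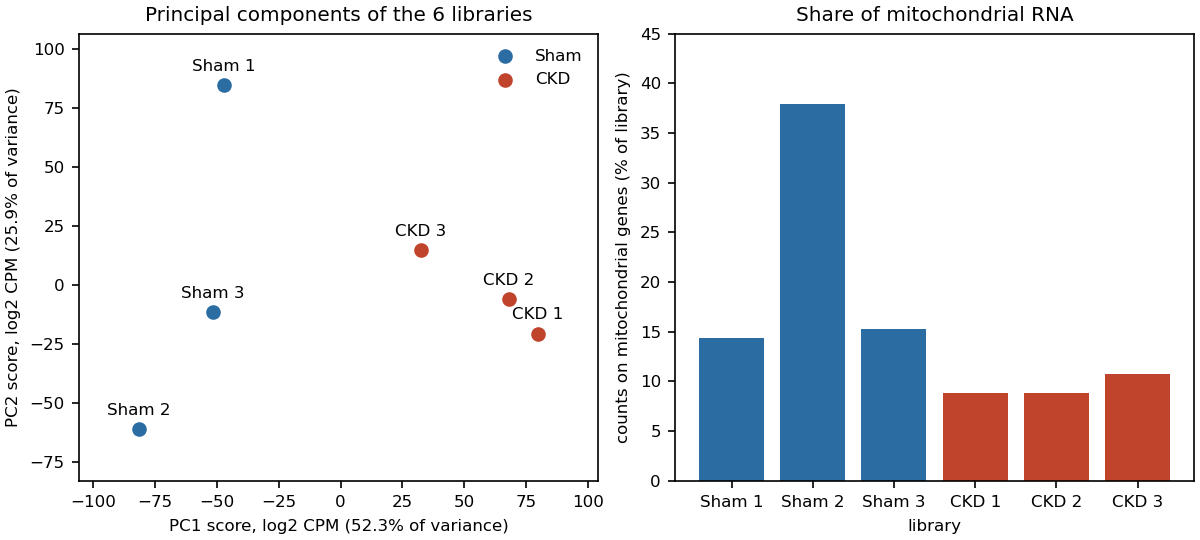
Left, scores of the 6 libraries on the first and second principal components of log2 CPM (52.3% and 25.9% of the variance). Right, percent of each library's counts on mitochondrial genes, 14.4, 37.9 and 15.3 in the 3 Sham libraries and 8.88, 8.83 and 10.8 in the 3 CKD libraries.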

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

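The removal of mitochondrial genes and limma-voom with library weights were chosen after the data were seen; the other settings were planned. All 587 genes kept their direction wherever they were tested, but the number past the threshold moved with the test and with the libraries. With library totals alone 2228 genes passed (2047 higher), with DESeq2 2497 (1379 higher, 1118 lower, all 587 among them), with limma-voom 195 (120 higher, 75 lower; 193 of them among the 587), against a fold of 1.5 there were 89 (52 higher, 37 lower), and at an adjusted p under 0.01 edgeR left 0 in either direction. With library weights the total was 487, with 186 higher and 301 lower and 304 shared. Leaving out 1 library gave 0 to 1711 genes (0 to 789 higher, 0 to 922 lower; without CKD 3, 413, with 73 lower), and group separation of 48.8% ran from 44.1% to 62.8%, the highest without Sham 1. Tests with 1 library less have fewer samples; otherwise the cause was not tested. The other settings gave 515 to 722 genes. Of the lists, 12 in place of 7 were called lower with library totals alone, 0 in total, higher or lower with an estimated correlation, and 7 with fry (7 higher, 0 lower). Limma-voom, with or without library weights, and the fit without robust empirical Bayes leave the log2 CPM used by camera unchanged. They gave the same camera values and were not counted for lists. Over named genes, 806 values kept their side of the threshold, 46 passed it and 173 no longer did. Over lists these numbers were 550, 18 and 44. Of both, 0 turned direction with a value past the threshold in either fit. Turns of direction with neither value past it, as for Acta2 and the proximal tubule list, were counted among the 806 and 550. The replicate numbers are not said to pair animals, and deviations of same-numbered libraries correlated at -0.21, 0.00 and -0.16; a model with the replicate block called 10 genes (4 higher, 6 lower), all among the 587, and the erythroid list as lower (camera adjusted p = 0.00957). Thinning to the smallest library left 562 genes, 546 of them shared, but totals differed too little for this to test depth.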

Other observations

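All tests in this part other than those of sequencing depth, gene length and the splits of the libraries were chosen after the result was seen, and the 6 added gene lists were written after values of most of their members had been looked at, so their p-values are not independent evidence. After their values were seen, a first test of nephron segments, on the straight-tubule list, was replaced, the rule for mitochondria gained the condition that the libraries overlap, and the glucocorticoid test was restricted to need members whose values had not been seen. By the first rules all 3 explanations had counted as fitting.

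Some genes of the circadian clock and some targets of PPAR-alpha, the receptor that turns on fatty acid use in fasting, fell in CKD. In camera with an estimated correlation neither list was called (adjusted p = 0.09 and adjusted p = 0.17). Of 18 clock genes 6 fell, namely Ciart, Usp2, Cry1, Cry2, Per1 and Nr1d1, and all 18 had a negative fold change. Per1 fell from 356 ± 99.7 to 97.9 ± 13.3 CPM and Ciart from 31.7 ± 11.5 to 1.97 ± 0.76 (SD, n = 3; edgeR adjusted p = 0.0318 and 0.0278). The activators Bmal1, Clock and Npas2 had log2 fold changes of -1.12 ± 0.33, -0.31 ± 0.35 and -0.37 ± 0.37 (SE; edgeR adjusted p = 0.0945, 0.635 and 0.594). Of 21 PPAR-alpha targets 20 had a negative fold change and 5 fell, namely Pdk4, Plin2, Pex11a, Angptl4 and Creb3l3. Plin2, a coat protein of lipid droplets, fell from 862 ± 579 to 85.4 ± 15.1 CPM (edgeR adjusted p = 0.0356). Medians were -1.32 for the clock list (-1.42 to -1.29 over the fits with 1 library left out) and -1.15 for PPAR-alpha targets (-1.52 to -0.97).

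Single genes that fell include Gadd45a (-2.40 ± 0.28), Btg2 (-2.06 ± 0.44) and Sik1 (-1.74 ± 0.21; log2 fold change ± SE, edgeR adjusted p = 0.0278, 0.0484 and 0.0278). They were picked after their values were seen and were not tested as a group. Of 15 glucocorticoid-induced genes 3 fell, Errfi1, Ddit4 and Per1 (median -1.06, or -0.68 without CKD 1; camera adjusted p = 0.09 with an estimated correlation). All 11 genes of the straight proximal tubule list had a negative fold change and 0 passed in edgeR (median -1.85, camera adjusted p = 0.00104; adjusted p = 0.40 with an estimated correlation). Without Sham 1 that median was -0.25 (camera adjusted p = 0.135).

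Chance and the grouping. The real grouping gave 587 genes in edgeR, and the highest of the other groupings of the 6 libraries into 3 and 3 gave 0 (up to 962 at an unadjusted p under 0.05). For the gene lists the real grouping called 20 and the others 10 to 19. Of the 10 groupings 1 gave as many genes and 1 as many lists, the real one; with 10 groupings a share under 0.05 cannot be reached.

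The Sham libraries spread more than the CKD libraries, with summed squares of deviations of log2 CPM 2.65 times as large. The ratio was 2.65 after thinning to equal totals, but totals differed too little for this to test depth. After removal of the trend with gene length it was 2.63, which argues against gene length as the cause of the spread. A different share of nephron segments in the pieces of tissue may account for part of it: over the Sham libraries the medians of the 7 nephron lists fixed beforehand had a mean SD of 0.96, against 0.43 for 16 pathway lists, a difference of 0.53 ± 0.12 (SE). Over the CKD libraries, looked at later, that difference was -0.11 ± 0.08. Both standard errors are over lists measured in the same libraries, so they do not measure the spread between pieces of tissue. The straight-tubule list, added later, spread as widely in CKD (-2.90, -0.81 and 0.62) as in Sham (2.81, 0.07 and -0.37). It therefore does not account for the wider spread in Sham. The convoluted tubule list, also added later, spread more in Sham (-0.11, -1.57 and 0.93) than in CKD (0.26, 0.36 and 0.48). Biological differences between animals stay open.

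All 13 mitochondrially encoded mRNAs had a negative fold change, and 12 were lower when adjusted over the list alone, but over all genes only Mt-atp8 passed in edgeR (-1.97 ± 0.36), with 2 passing without Sham 1, 0 without any other library, and 13 in DESeq2. Their median was -1.66, or -1.10 without Sham 2, with an adjusted p = 0.22 in camera with an estimated correlation. Sham 2 alone does not account for the lower share of mitochondrial counts, since the lowest share of the remaining Sham libraries was 1.33 times the highest CKD share. Fewer mitochondria, or fewer cells rich in them, may be a cause and cannot be told apart from a change of mitochondrial transcripts alone: the fall exceeded that of nuclear genes of oxidative phosphorylation by 1.15 ± 0.68 (SE; -1.15 as CKD minus Sham), within 2 standard errors, although the libraries of the groups did not overlap. Without Sham 2 the gap was smaller, -0.47 ± 0.16, and passed 2 standard errors with no overlap. That value rests on 2 Sham libraries, too few to decide. With any other library left out the gap stayed within 2 standard errors, also with no overlap. The test over all 6 libraries cannot tell, and RNA integrity, not used here, stays open.

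For the clock and PPAR-alpha genes 3 explanations cannot be told apart. The ± values in this paragraph are standard errors from resampling genes, not libraries, so they do not measure the spread between samples. Whether loss of proximal tubule cells contributes to the fall of PPAR-alpha targets was not settled. The proximal tubule list itself had a median of -0.11 and was not called (camera adjusted p = 0.767). The convoluted tubule list had a median of 0.42 and the straight-tubule list one of -1.85, or -0.25 without Sham 1. The median of the targets lay -1.04 ± 0.38 from that of the proximal tubule list. This gap did not exceed the bound of 0.5 by 2 standard errors. Kidneys taken at different times of day could shift clock genes, and the activators were predicted to move the other way in that case. Their median of -0.37 ± 0.34 lay within 2 standard errors of 0, so this test cannot tell. Lower glucocorticoid exposure, or feeding, could lower both sets: glucocorticoid-induced genes off the clock list had a median of -1.01 ± 0.15 over 14 genes, but the values of all but 3 of them (median -1.60) had been seen when the list was written, and 3 are too few by the rule, so the explanation stays open. The time of day, feeding state and hormone levels are not given in the sources used here.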
